A study of Drosophila melanogaster with 30 samples.

How the data were processed

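Brains of male Drosophila melanogaster were dissected in phosphate-buffered saline into RNAlater, 30 brains per replicate, and RNA was extracted with TRIzol and a spin column and treated with DNase, per the labels' protocols. Libraries were made with a kit for polyadenylated RNA that keeps strand and were sequenced as paired-end reads on a NextSeq 2000, per the labels. There were 10 groups of 3 libraries, which combined 5 genotypes (Canton-S wild type and mutants of Or47b, Or67d, fru and dsx) with group or single housing. Groups and replicates were taken from the column names, which carry genotype, housing and replicate number.

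The first deposited table gives expected (estimated) counts per feature, since 11.9% of its values were not whole (compared with the nearest integer at a tolerance of 0), and it is not scaled between libraries. Per the submitters' processing notes, STAR, Salmon and DESeq2 were used with the genome build BDGP6, and no versions, settings or annotation release are stated. It is not stated whether the counting used strand, so genes that overlap another gene are named as such. The second deposited table holds scaled signal values, called normalized counts by its name, for 11335 features, of which 11314 were genes. The ratio of this deposited signal to the estimated counts differed from gene to gene within a library, so more than 1 size factor per library was applied, and neither the method nor the filter is stated. Library totals of that table were 40.3 to 50.1 M. Another deposited table assigns each library to AC or notAC in a column called dissection, without a key.

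The table of estimated counts has 24278 features. The 17895 with FlyBase gene identifiers entered the main tests, and 17855 of these matched the Ensembl annotation of release 115, from which symbols, positions and overlaps were taken. The other 6383 features, among them 5736 transposon insertions, were left out of the main tests and tested only as an alternative, because copies of a transposon share reads. Features that are not genes took 0.6% to 1.38% of a library's counts, and ribosomal RNA genes took 0.163% to 2.02%. Total counts per library ranged from 37612929 to 120862305 (median 48.3 M), and gene counts from 37.3 to 120 M (median 47.9 M). A floor of 3 counts per library or over a group's libraries gives the limit beside values of 0 and covers counting error only. No pair of libraries had identical counts.

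Counts were rounded and tested in R 4.3.3 with edgeR 4.0.16. The filter filterByExpr on the 10 groups left 11269 genes, scaling was by trimmed mean of M values (TMM), and quasi-likelihood F tests were taken from 1 fit of all 30 libraries with a term for each group and a term for the AC batch. The common dispersion was 0.0262, with 19 residual degrees of freedom and a median of 3.93 prior degrees of freedom. P values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Changes are edgeR log2 fold changes with standard errors from the fit, and group values are CPM of the total TMM-scaled gene counts as mean and SD. There were 18 comparisons, which were the housing effect (SH minus GH) in each genotype, its average over the 5 genotypes, each mutant against CS in each housing, and each mutant's housing effect minus that of CS.

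Gene lists were tested with limma 3.58.1 on log2 CPM with a prior count of 2. camera was run with a preset inter-gene correlation of 0.01 and again with an estimated one, and its p values were adjusted over the 36 lists of a comparison. fry was run as another test, whose p asks whether a list's genes move one way on balance and whose mixed p asks whether they change in either direction. Neither compares the list with other genes. Calls among a list's members are given over all genes tested and adjusted over the list alone. A pattern on the name defined the cytochrome P450 list, so the cyclophilin genes Cyp1 and Cyp40 were in it, the symbols Trhn, Mfe and tequila of other lists matched no gene, and tsx is another name of Obp99b, so that gene counted once. Overlaps between gene sets were tested with Fisher's exact test, 2-sided, over the genes tested.

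Genes were named by a rule. For CS housing these were the 12 higher and 12 lower genes with the smallest adjusted p, for each mutant's housing effect 6 and 6, for the averaged effect 8 and 8 with the same sign in all 5 genotypes, and for the interactions 4 and 4. For each mutant against CS they were 8 and 8 genes called in the same direction in both housings, with every library of one group above every library of the other. The genes for housing in CS and in each mutant also had every library of one housing above every library of the other. The rule also took 10 genes called for housing in at least 2 genotypes, the mutated genes and w, and up to 4 called members of each list. Where such genes were many, some stand only in the counts. The groups, the tests with the batch term, the gene lists and this rule were chosen before the data were examined. CG14125 and the overlaps of genes were noted after their values were seen.

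The alternatives chosen beforehand were DESeq2 size factors in edgeR, no filter on low counts, DESeq2 1.42.0 with its Wald test, no batch term, a block for the replicate number, a fit of only the groups compared, and each library left out in turn. Chosen after the data were seen were a test of all features with transposons, a fit of the 24 notAC libraries, limma on log2 of the deposited signal plus 1, the log2 share of mitochondrially encoded counts as a covariate, the counts of list members under each scaling and, for dsx, with that covariate, and the sign of change between single AC libraries. Other splits of the samples were fitted as controls, 10 for each comparison of 3 libraries with 3, 25 for each interaction and 50 for the averaged effect, the last 2 kinds with housing exchanged among the libraries of each genotype. Comparisons that share the CS libraries were set beside simulated unchanged groups.

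The scripts' tests were run on simulated counts with 200 genes changed. For CS housing, 175 of 200 were recovered with 16 false calls over 10852 genes, at 37, 41, 47 and 50 of 50 for changes of 1.5, 2, 4 and 8-fold. For fru against CS in SH, 172 were recovered with 13 false calls, and for the dsx interaction 148 with 4 false calls. On unchanged simulated data 0 genes were called. Figures were drawn with Python 3.11.15.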

Results

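Polyadenylated RNA from pools of 30 male Drosophila brains was sequenced in 10 groups of 3 libraries, 30 libraries in all. The groups were wild-type Canton-S (CS) males and males mutant for Or47b, Or67d, fru or dsx, each kept in groups (GH) or alone (SH). Or47b and Or67d encode odorant receptors for fly pheromones, and fru and dsx encode transcription factors of the sex determination pathway. Total estimated counts per library ranged from 37612929 to 120862305, with a median of 48.3 M, and 3 counts in a library equalled 0.0282 to 0.0785 counts per M of TMM-scaled gene counts (CPM, where M is the SI prefix mega). Of 17895 gene rows, 11269 passed the filter on low counts and were tested. Mitochondrially encoded genes took 2.49% to 14% of a library's counts (median 6.96%). A deposited table assigned 6 libraries to a dissection batch called AC, namely CS GH replicate 3, CS SH replicate 2 and the third replicate of each Or47b and fru group, and 24 libraries to notAC. The main tests carried a term for this batch, which was itself called in 6161 of the 11269 genes, and because the AC libraries came from 3 of the 5 genotypes the values within notAC are given beside counts that moved with it. Adjusted p values below come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named. They measure the spread between these pools of brains, whereas detection floors cover counting error only.

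The targeted genes were read first, as a check on the labels. fru (FBgn0004652, 3R 18414273 to 18545586, Ensembl annotation of BDGP6) fell from 179 ± 21 CPM (SD, n = 3) in CS GH to 28.8 ± 2.15 in fru GH, a log2 change of -2.64 ± 0.126 (SE, edgeR adjusted p = 2.6e-13). In SH it fell from 173 ± 3.39 to 26.3 ± 5.2 CPM (log2 -2.72 ± 0.127, adjusted p = 1.7e-13). dsx fell from 13.5 ± 0.791 to 9.41 ± 0.274 CPM in dsx GH (log2 -0.51 ± 0.17, adjusted p = 0.0334) and from 18.7 ± 2.92 to 9.48 ± 0.989 CPM in dsx SH (log2 -0.975 ± 0.171, adjusted p = 0.000131). Or67d had 0 counts in all 6 Or67d libraries against 0.323 ± 0.076 CPM in CS GH and 0.312 ± 0.185 in CS SH, which is at least 17.5-fold lower in GH and at least 14.5-fold lower in SH against a floor of 3 counts over the group. Or67d was also lower in the dsx mutant, at 0.0393 ± 0.0158 CPM in GH (log2 -2.90 ± 0.518, adjusted p = 0.000494) and 0.0569 ± 0.0218 in SH (log2 -2.29 ± 0.515, adjusted p = 0.00166). Or47b was near the floor in the brain and was not tested, with 1 count over the CS GH libraries, 5 over CS SH and 0 over both Or47b groups, so its loss was not detectable at this depth. The eye colour gene white (w), a marker of the strain, stood at 9.88 ± 0.802 CPM in CS GH and 0.374 ± 0.111 in the dsx GH mutant, whose genotype is labelled w-. It was also low in the Or67d mutant, labelled w+, at 1.76 ± 0.211 CPM in GH (log2 -2.40 ± 0.215, adjusted p = 2.75e-08) and 1.69 ± 0.412 in SH (log2 -3.09 ± 0.22, adjusted p = 5.98e-10). fru transcript did not change past the threshold in the Or47b, Or67d or dsx mutant, and dsx transcript did not in the Or47b, Or67d or fru mutant.

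**Figure D1:**
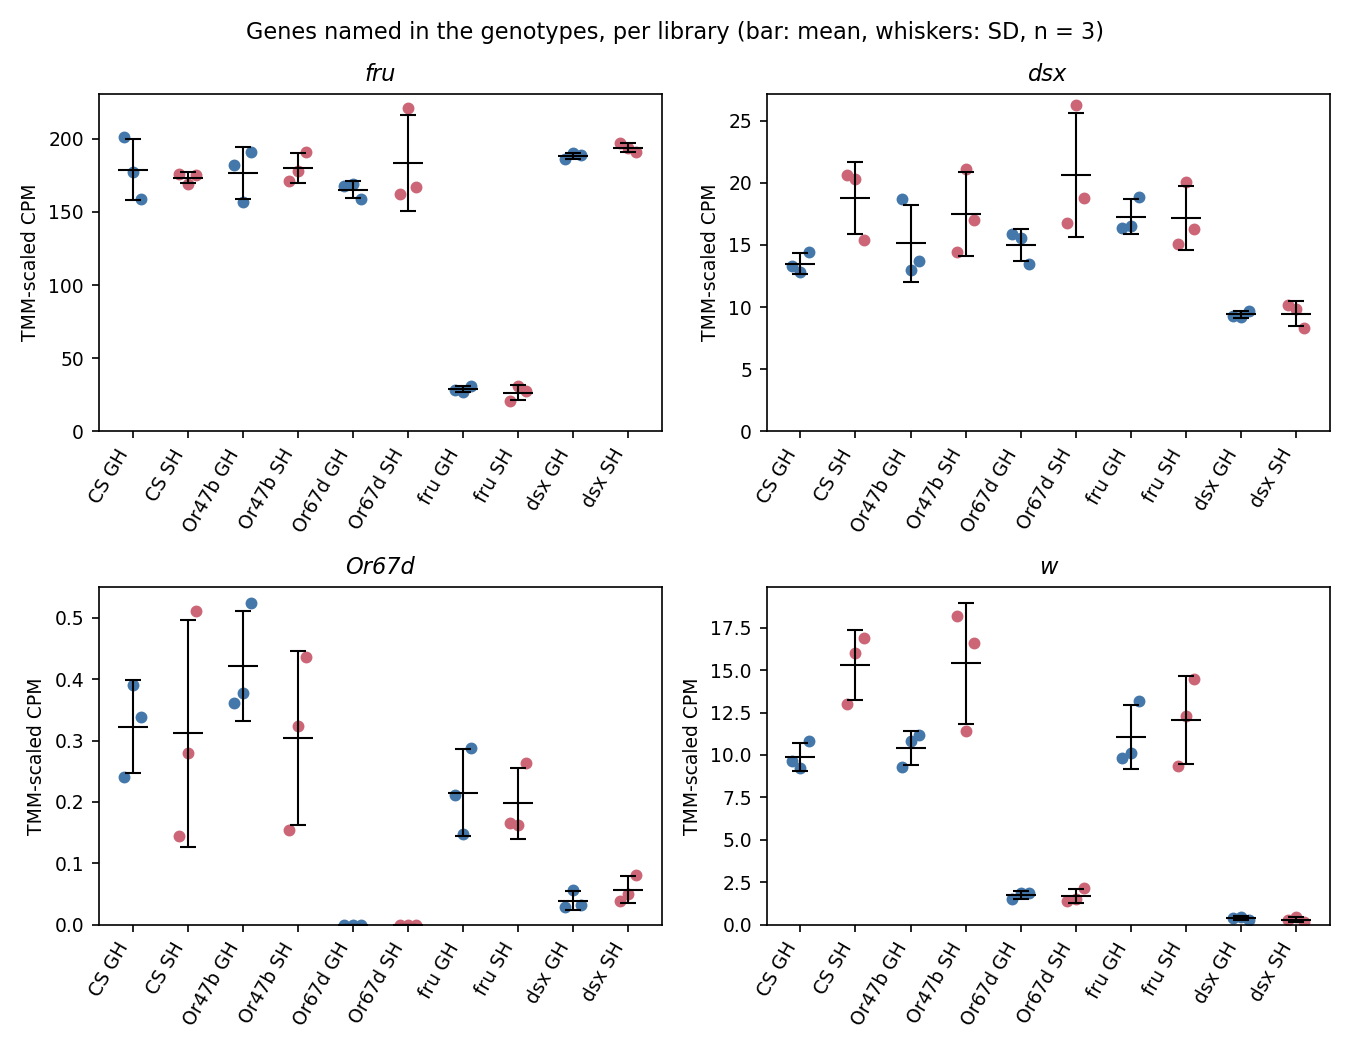
Expression of fru, dsx, Or67d and w (y axis, CPM) in the 10 groups of genotype and housing (x axis), with points for the 3 libraries of a group and bars for the mean and SD. fru drops to 28.8 and 26.3 CPM in fru mutants, and Or67d has 0 counts in Or67d mutants.

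The first comparison asked which genes of the wild-type male brain differ between isolated and grouped flies. In CS males, the neuropeptide gene Dsk (FBgn0000500, 3R 4189692 to 4190260), a relative of cholecystokinin that acts in satiety and aggression, fell from 125 ± 8.86 CPM (SD, n = 3) in GH to 41.5 ± 1.96 in SH, a log2 change of -1.60 ± 0.168 (SE, edgeR adjusted p = 1.1e-05). The insulin-like peptide gene Ilp5 (FBgn0044048, 3L 9823349 to 9823897) rose from 22.3 ± 6.65 to 72.3 ± 5.71 CPM (log2 1.69 ± 0.208, adjusted p = 7.77e-05), and Mip, which encodes myoinhibitory peptides, rose by a log2 change of 0.95 ± 0.144 (adjusted p = 0.00095). CG10513 (FBgn0039311, 3R 25275790 to 25277212) had the smallest adjusted p, rising from 37.9 ± 1.53 to 102 ± 9.44 CPM (log2 1.42 ± 0.129, adjusted p = 1.47e-06). CG9377 rose by 1.79 ± 0.201 (adjusted p = 2.3e-05), the UDP-glycosyltransferase gene Ugt35B1 by 1.09 ± 0.123 (adjusted p = 2.3e-05) and the acyl-CoA synthetase family gene Acsx3 by 1.15 ± 0.154 (adjusted p = 0.000186). Of the 24 genes named by the rule for this comparison, the rest that rose were CG8547, CG31869, Achl, CG1673, CG6040 and the clock gene cry, with log2 changes from 0.72 to 1.21.

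In SH, 107 genes were higher and 103 lower in CS at an adjusted p under 0.05 (2087 at an unadjusted p under 0.05), 53 of them by over 2-fold. The genes named above and below for CS kept their calls with each of the 6 CS libraries left out, except where a library is named. The rule for this comparison took only genes whose SH libraries all lay above or all lay below the GH ones, which favours this. With only the CS groups fitted, where 17 genes were called, the calls of Ilp5, Ugt35B1, Acsx3, Mip, CG8547, CG31869, Achl and CG6040 were lost, and those of CG8547, Achl and CG1673 were lost without the batch term. The count itself rested on single libraries, at 84 without CS GH replicate 1, 436 without GH replicate 2, 125 without GH replicate 3, 436 without SH replicate 1, 52 without SH replicate 2 and 127 without SH replicate 3. It was 70 among the notAC libraries, which leave 2 CS libraries per housing, 46 without the batch term and 663 with DESeq2's Wald test. Mitochondrially encoded counts took 4.37% to 10.1% in CS GH and 2.95% to 4.53% in CS SH, and with that share as a covariate 70 genes were called.

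Antimicrobial peptide genes were among the genes that fell in isolated CS males. DptA (FBgn0004240, 2R 18865765 to 18866260) dropped from 11.3 ± 5.98 CPM in GH to 0.112 ± 0.145 in SH (log2 -6.83 ± 1.08, edgeR adjusted p = 0.00124), and DptB dropped from 8.62 ± 1.88 to 0.0546 ± 0.0272 CPM (log2 -7.38 ± 1.16, adjusted p = 0.00124). Mtk (log2 -4.64 ± 0.785, adjusted p = 0.0025) and the Bomanin gene BomBc1 (log2 -3.26 ± 0.562, adjusted p = 0.00274), which also encode secreted immune peptides, were lower, as was the attacin gene AttC. SPH93, a serine protease homologue, dropped by a log2 change of -5.82 ± 1.04 (adjusted p = 0.00359), and CG4757, GNBP-like3, IM18, CG42711 and CG14024 were also lower. The calls of DptA, BomBc1, CG4757, GNBP-like3, IM18, CG42711 and CG14024 were lost with only the CS groups fitted. DptB overlaps CG43109, AttC overlaps CG4744 and IM18 overlaps CG10332, so reads of these pairs cannot be told apart without strand. Of 40 immune effector genes tested, 15 were lower and 0 higher, or 32 lower when adjusted over the list alone, with a median log2 change of -2.05. The count of 15 became 7 without CS GH replicate 1 and 7 without CS SH replicate 3. camera put the immune list below other genes (adjusted p = 3.72e-24, but adjusted p = 0.101 with an estimated correlation).

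**Figure D2:**
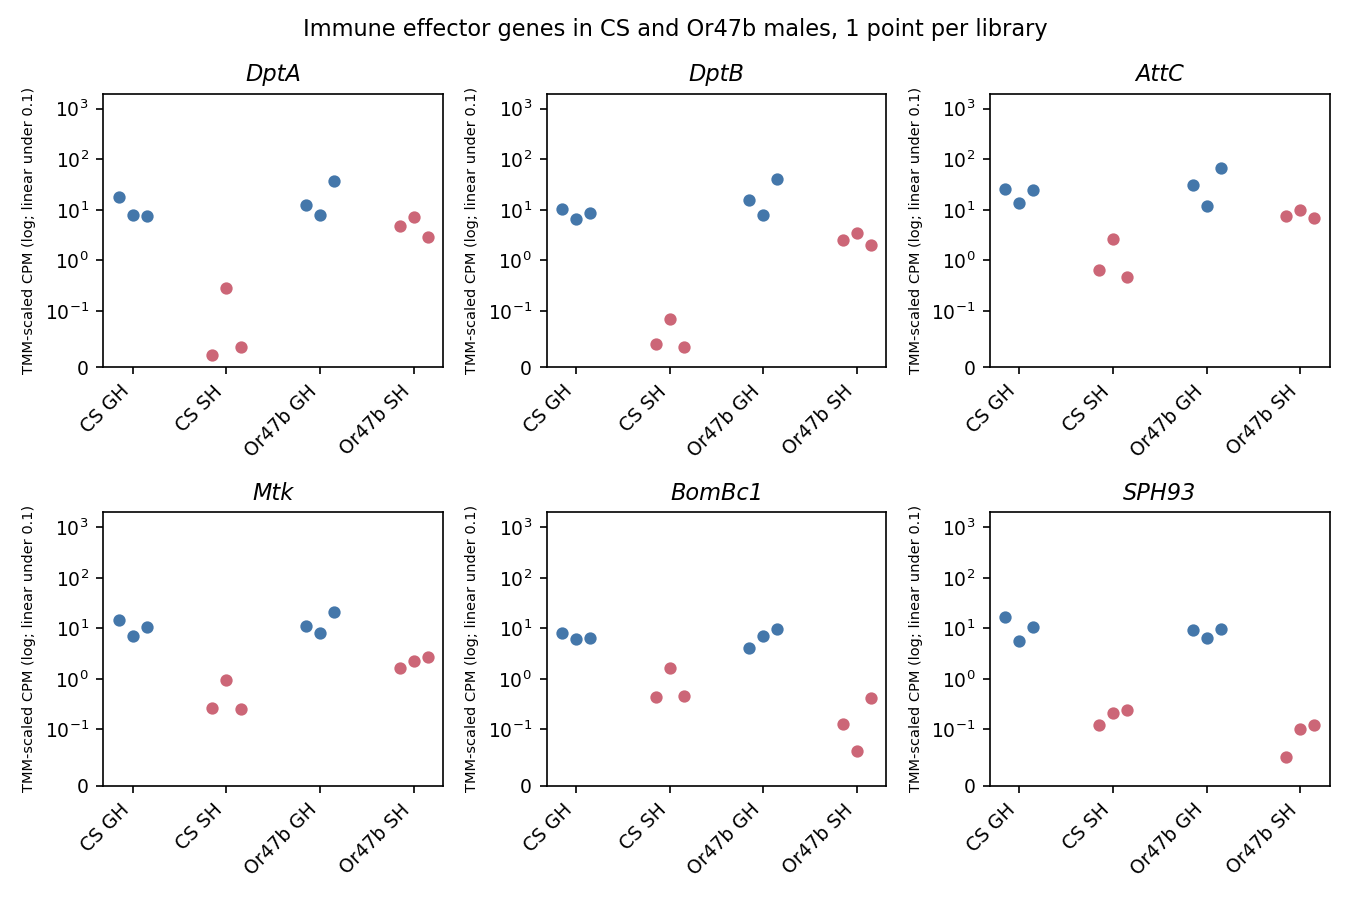
Expression of 6 immune genes (y axis, CPM, logarithmic above 0.1 and linear below) in group-housed and single-housed CS and Or47b males (x axis), with points for the 3 libraries of each group. DptA falls from a mean of 11.3 to 0.112 CPM in CS males.

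Clock genes formed another part of the CS housing change. cry (FBgn0025680, 3R 19212154 to 19215442), the blue-light receptor of clock neurons, rose from 43.3 ± 1.13 to 80.9 ± 4.4 CPM (log2 0.90 ± 0.113, edgeR adjusted p = 9.29e-05). It overlaps vib and lncRNA:CR46393. Clk rose by 0.85 ± 0.154 (adjusted p = 0.00423), whereas vri fell by a log2 change of -1.60 ± 0.302 (adjusted p = 0.00598) and tim by -1.09 ± 0.232 (adjusted p = 0.0141). The call of tim was lost without CS GH replicate 3 and without CS SH replicate 3, with a highest adjusted p of 0.0846, and the calls of Clk, vri and tim were lost among the notAC libraries. Of 8 core clock genes, 2 were higher and 2 lower (2 higher and 4 lower when adjusted over the list alone), so the list as a whole did not move one way (camera adjusted p = 0.675). Of 12 activity-regulated genes, which are transcribed after neuronal firing, 5 were lower (7 when adjusted over the list alone; camera adjusted p = 8.52e-08, but adjusted p = 0.101 with an estimated correlation). That count was 3 without CS GH replicate 1, 2 without GH replicate 3, 1 without SH replicate 2 and 3 without SH replicate 3. Of 12 juvenile hormone genes, 2 were higher, among them the epoxide hydrolase gene Jheh1 (log2 0.67, adjusted p = 0.00249), and 3 when adjusted over the list alone. One of these calls was lost without CS GH replicate 1 and without CS SH replicate 2, which left 1. Jheh1 overlaps asRNA:CR46485 and was lost without the batch term or with only the CS groups fitted. camera gave an adjusted p of 0.00415 for the list, and 0.101 with an estimated correlation.

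**Figure D3:**
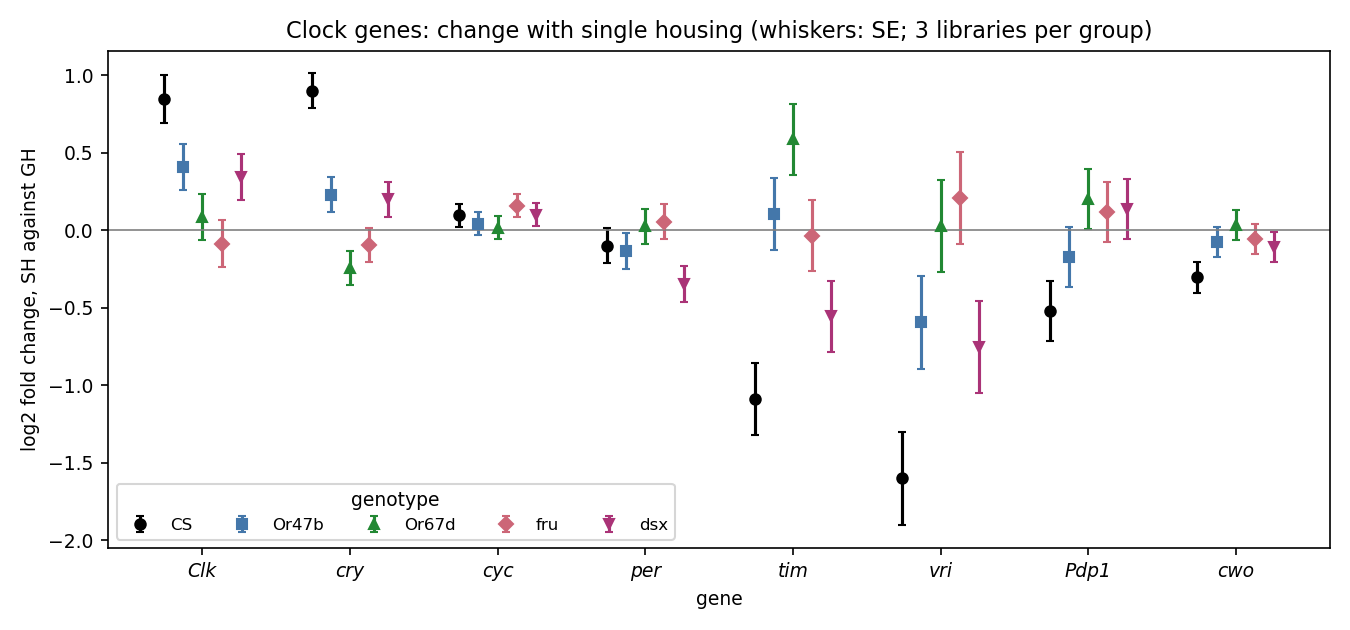
Log2 change between single-housed and group-housed males (y axis) of 8 clock genes (x axis) in the 5 genotypes, with points for the estimate and bars for its SE. In CS, cry and Clk lie above 0 (0.90 and 0.85) and vri and tim below it (-1.60 and -1.09).

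Housing in the Or47b mutant tested whether the response persists without this pheromone receptor. Dsk fell from 161 ± 38.4 CPM in GH to 55.8 ± 5.57 in SH (log2 -1.52 ± 0.167, SE, n = 3 per group, edgeR adjusted p = 2.61e-05). The Bomanin genes BomBc1 (log2 -5.21 ± 0.658, adjusted p = 0.000198), BomS1 (log2 -3.67 ± 0.554, adjusted p = 0.00205) and BomS2 (log2 -2.58 ± 0.393, adjusted p = 0.00205) fell as well, and GNBP-like3 fell from 3.72 ± 1.56 CPM to 0.00856 ± 0.0148 (adjusted p = 2.61e-05). Acsx3 rose by 1.05 ± 0.152 (adjusted p = 0.00148). Mip rose by 0.77 ± 0.144 (adjusted p = 0.0136), a call lost without Or47b GH replicate 1, GH replicate 3, SH replicate 1 or SH replicate 2. In all, 5 genes were higher and 19 lower (484 at an unadjusted p under 0.05). Without GH replicate 3, SH replicate 1, SH replicate 2 or SH replicate 3 the total of 24 became 12, 11, 10 and 10, and among the notAC libraries it was 5. It was 9 without the batch term and 42 with DESeq2's Wald test. Of the 40 immune effector genes, 10 were lower (31 when adjusted over the list alone), with 4 lower without SH replicate 1, 4 without SH replicate 2 and 6 without SH replicate 3. camera placed the list below other genes with the preset correlation (adjusted p = 2.2e-58) and with an estimated one (adjusted p = 0.00452).

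In the main test, few genes were called for housing in the Or67d, fru and dsx mutants, and Dsk was among them each time. Dsk fell by a log2 change of -1.66 ± 0.168 in Or67d (edgeR adjusted p = 1.11e-05), -1.80 ± 0.168 in fru (adjusted p = 2.36e-06) and -1.83 ± 0.169 in dsx (adjusted p = 1.79e-06), with n = 3 per group. The other calls in Or67d were CG1673, which rose by 1.06 ± 0.176, and the haemocyte gene Hml, which fell by a log2 change of -0.94 ± 0.158, both at an adjusted p of 0.0181. CG1673 was lost without Or67d GH replicate 2, GH replicate 3 or SH replicate 1, and Hml without GH replicate 2, GH replicate 3, SH replicate 2 or SH replicate 3 (highest adjusted p 0.233). In the fru mutant, CG34166 rose by 2.19 ± 0.288 (adjusted p = 0.000587) and the peroxiredoxin gene Prx2540-2 by 1.52 ± 0.225 (adjusted p = 0.00192). CG4577 fell by a log2 change of -0.89 ± 0.12 (adjusted p = 0.000588) and the trehalase gene Treh by -0.58 ± 0.0911 (adjusted p = 0.00338; it overlaps Rbpn-5). CG4577 was the other call in dsx (log2 -0.754 ± 0.12, adjusted p = 0.0114), lost without any of the 3 GH libraries, SH replicate 1 or SH replicate 3.

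The counts in these 3 mutants were 1 higher and 2 lower in Or67d (340 at an unadjusted p under 0.05), 13 higher and 6 lower in fru (1186) and 0 higher and 2 lower in dsx (382). DESeq2's Wald test called 18, 82 and 26 genes in them, and edgeR with only the groups compared called 0, 5 and 57. In Or67d, 1 gene was called without GH replicate 2 and 7 among the notAC libraries, and in dsx 5 among the notAC libraries, although all libraries of these 2 mutants are notAC. In fru the 19 calls became 5 without GH replicate 1, 7 without GH replicate 2, 135 without SH replicate 2 and 7 without SH replicate 3, and 10 among the notAC libraries. In dsx the count was 4 without SH replicate 2 and 1 without GH replicate 1, GH replicate 2, SH replicate 1 or SH replicate 3. With the deposited normalized values and limma, 1 gene was higher and 8 were lower in Or67d. No immune effector gene passed the edgeR threshold over all genes in these 3 mutants. Adjusted over the list alone, 1 was lower in Or67d, 0 in fru and 11 in dsx, where camera gave an adjusted p of 7.91e-19 (0.252 with an estimated correlation). DptA and DptB were already low in Or67d GH, at 0.173 to 0.3 and 0.0187 to 0.307 CPM. They stood at 7.64 to 18.2 and 6.72 to 10.5 CPM in CS GH, so their fall with isolation could hardly be read in Or67d. In dsx, 9 of 19 heat shock genes were lower when adjusted over the list alone and 0 over all genes.

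Averaging the housing effect over the 5 genotypes asked which genes change on average. Large changes in 1 or 2 genotypes can set such a mean, so a call does not show a response in each genotype. Dsk fell by a log2 change of -1.68 ± 0.075 (edgeR adjusted p = 4.92e-13) over 15 libraries per housing. Ilp5 rose by 0.86 ± 0.091 (adjusted p = 5.12e-06), and its level was higher in SH in each genotype's mean. BomBc1 fell by a log2 change of -2.82 ± 0.255 and GNBP-like3 by -3.20 ± 0.288 (both adjusted p = 4.38e-07), BomS2 by -1.65 ± 0.169 (adjusted p = 3.77e-06) and the immune peptide gene Dso2 by -1.32 ± 0.163 (adjusted p = 4.98e-05). Tested by genotype, BomBc1, GNBP-like3, BomS2 and Dso2 were called only in CS and Or47b. CG1673 (0.63 ± 0.0787, adjusted p = 4.98e-05), atk (0.91 ± 0.122, adjusted p = 9.86e-05) and Cyp309a1 (0.89 ± 0.129, adjusted p = 0.000243) rose, and CG4577 fell by a log2 change of -0.45 ± 0.0534 (adjusted p = 3.19e-05). atk overlaps CG42764 and Uhg8, and the calls of CG1673 and atk were lost without the batch term. The activity-regulated transcription factor gene sr fell by a log2 change of -1.10 (adjusted p = 0.000135).

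The averaged test called 63 genes higher and 81 lower (1076 at an unadjusted p under 0.05), with no condition on the sign in each genotype. It called 104 in all among the notAC libraries, 53 without the batch term and 230 with DESeq2's Wald test. Of the 40 immune effector genes, 24 were lower (33 when adjusted over the list alone; camera adjusted p = 5.37e-62, and 0.00323 with an estimated correlation). Of the 12 activity-regulated genes, 5 were lower (9 when adjusted over the list alone; camera adjusted p = 2.23e-12, and 0.0259 with an estimated correlation). With the call in Or47b males, these were the 3 camera calls of all comparisons that held with an estimated correlation. Genotype by genotype, 16 of the 236 genes called in any genotype were called in the same direction in 2 or more, 12 lower and 4 higher, and 2 were called in opposite directions, CG9377, higher in CS and lower in fru, and CG14125, lower in CS and higher in Or47b. In CS, CG14125 was expressed almost only in the AC library of each housing, with levels given under other observations, so its call there rests on these libraries. Dsk was called in all 5 genotypes and SPH93 in CS, Or47b and fru, although SPH93 was lost in Or47b without any 1 of its SH libraries and in fru without any 1 library. CS and Or47b shared 11 lower genes (0.174 expected, adjusted p = 2.45e-17) and 3 higher (0.0475, adjusted p = 4.38e-05) by Fisher's exact test. Genes are not independent, as with immune genes among the 11, which these p values ignore. Here housing changes correlated at 0.0204 across genes (-0.0722 to 0.171 over 10 pairs).

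**Figure D4:**
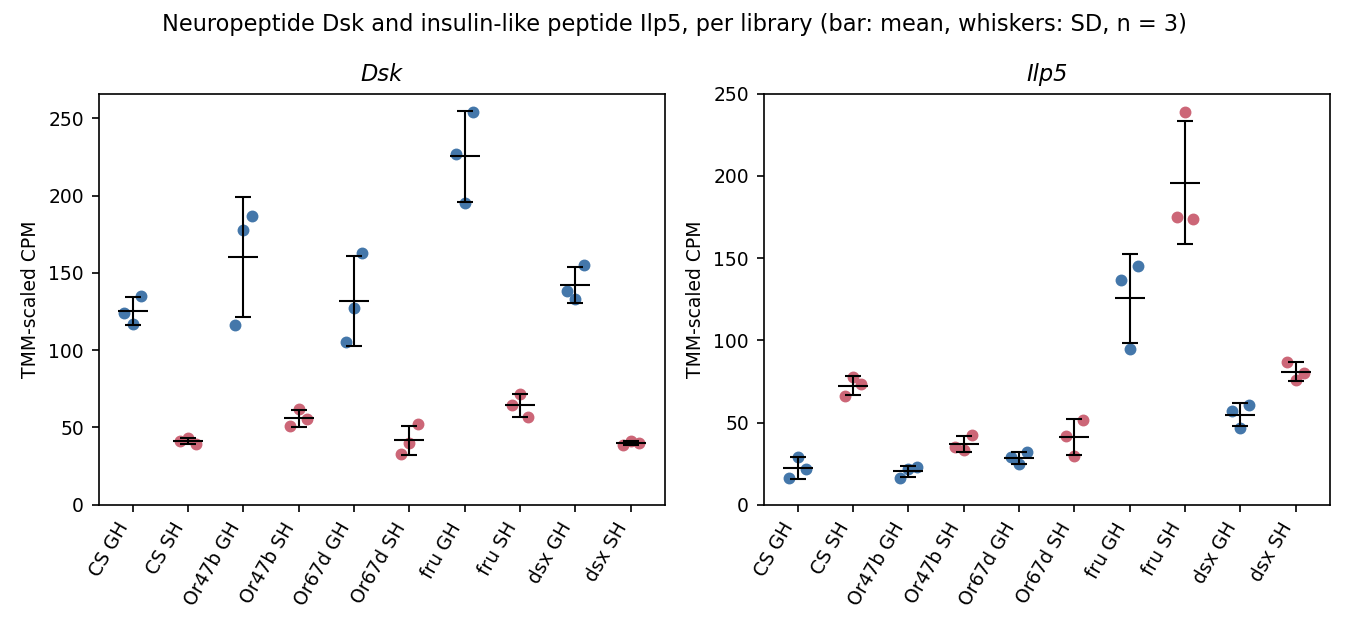
Expression of the neuropeptide genes Dsk and Ilp5 (y axis, CPM) in group-housed and single-housed males of the 5 genotypes (x axis), with points for the 3 libraries of a group and bars for the mean and SD. Dsk is lower in single-housed males in each genotype, as in CS with 125 against 41.5 CPM.

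The Or47b mutant was compared with CS in each housing. Effects of the mutated gene and of a differing strain background cannot be told apart in this comparison, nor in those of the other mutants with CS below. NT5E-2 and prg, named below, were called in the same direction in every mutant in both housings. The adenylate kinase gene Adk3 (FBgn0026602, 2R 7243024 to 7245776) rose by a log2 change of 1.53 ± 0.066 in GH and 1.44 ± 0.0658 in SH (SE, n = 3 per group, edgeR adjusted p = 2.31e-13 and 4.28e-13). Septin5 (3.32 ± 0.162 and 3.61 ± 0.164), the nucleotidase gene NT5E-2 (2.75 ± 0.155 and 3.19 ± 0.156) and Gadd45 (2.10 ± 0.168 and 2.14 ± 0.168) rose in both housings, NT5E-2 with an overlap of CG43110. CG31683 fell from 20.2 ± 2.03 CPM to 0.22 ± 0.103 in GH (log2 -6.45 ± 0.392, adjusted p = 5.45e-11) and by -7.00 ± 0.419 in SH, although it overlaps CG31688. prg fell by a log2 change of -1.35 ± 0.0785 and -1.30 ± 0.0785, and Tdc1, a tyrosine decarboxylase gene, by -3.41 and -3.25, although Tdc1 overlaps Rpp25. The insulin-like peptide gene Ilp3 fell by -1.63 and -1.70, and Cyp6a20, a cytochrome P450 gene tied to aggression after isolation, rose by 1.51 and 1.70.

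Against CS, 194 genes were higher and 233 lower in Or47b GH, and 473 higher and 477 lower in Or47b SH. Of these, 118 were higher and 150 lower in both housings. In GH the 427 calls became 235 without Or47b GH replicate 3, 284 among the notAC libraries, 230 without the batch term and 139 with only the groups compared. In SH the 950 became 376 without CS SH replicate 2, 473 without CS SH replicate 3, 407 without Or47b SH replicate 2 and 327 without Or47b SH replicate 3. They were 304 among the notAC libraries, 306 without the batch term, 534 with only the groups compared and 356 with the mitochondrial share as a covariate. Of 20 muscle marker genes, 15 were lower in SH (16 when adjusted over the list alone; camera adjusted p = 2.98e-09, but adjusted p = 0.882 with an estimated correlation). That count was 2 without CS SH replicate 3, 8 without Or47b SH replicate 1, 3 without SH replicate 2 and 7 without SH replicate 3. Muscle markers were also lower in other mutants in SH, 10 in fru with 1 higher (12 and 1 when adjusted over the list alone) and 12 in dsx (16), with camera adjusted p values of 0.00669 and 0.000869, and 0.921 and 0.684 with an estimated correlation. Without CS SH replicate 3, which all 3 comparisons share, these became 1 and 6. In fru they were also 2, 1 and 6 without SH replicates 1, 2 and 3, the last of which ended the 1 higher call, and in dsx 1 with the mitochondrial share as a covariate. Of 77 cytochrome P450 genes, 7 were higher and 5 lower in GH (8 and 8 when adjusted over the list alone), and the 5 became 3 without CS GH replicate 1, 3 without GH replicate 2 and 9 without GH replicate 3.

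The Or67d mutant was compared with CS in the same way and with the same limit on strain background. AstC-R1 (FBgn0036790, 3L 18560258 to 18576326), a receptor gene for the neuropeptide allatostatin C, rose from 25.7 ± 3.81 CPM in CS GH to 83.4 ± 3.49 in the mutant (log2 1.64 ± 0.0915, edgeR adjusted p = 7.41e-12) and by 1.81 ± 0.0921 in SH (adjusted p = 1.24e-12). The laminin gene LanA rose by 2.32 ± 0.155 and 1.87 ± 0.153, and Bmcp, which encodes a mitochondrial carrier, by 1.07 ± 0.0766 and 1.14 ± 0.0765. p24-2 had 0 counts in the CS groups and 124 ± 21.5 and 117 ± 20.1 CPM in Or67d GH and SH, at least 5.36e+03-fold and 5.82e+03-fold higher, although it overlaps Unc-115b. The receptor gene mthl8 had 0 counts in the Or67d groups, at least 1.47e+03-fold lower in GH and 1.35e+03-fold lower in SH. The odorant receptor gene Or63a fell from 9.69 ± 0.533 to 0.0128 ± 0.0221 CPM in GH (adjusted p = 6.99e-18), and CG7386 by a log2 change of -5.51 ± 0.228 and -5.96 ± 0.239 in GH and SH.

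In Or67d GH, 578 genes were higher and 523 lower than in CS, and in SH 280 and 356. Of these, 198 were higher and 203 lower in both housings. In GH the 1101 calls became 660 without Or67d GH replicate 3 and 608 without the batch term. In SH no single library moved the 636 calls by over 1.5 times, and with only the groups compared they were 134. Immune effector genes were lower in GH, 15 of 40 against 2 higher (24 and 2 when adjusted over the list alone; camera adjusted p = 5.68e-08, but adjusted p = 0.664 with an estimated correlation), and 9 were lower without CS GH replicate 1 or without Or67d GH replicate 3. In SH, 1 was higher and 0 lower (1 and 0 when adjusted over the list alone), and the 1 was lost without CS SH replicate 1, CS SH replicate 3 or Or67d SH replicate 1. Of 32 glutathione S-transferase genes, 8 were higher and 1 lower in GH (10 and 1 when adjusted over the list alone; camera adjusted p = 0.000883, but adjusted p = 0.664 with an estimated correlation), with GstD9 higher by 2.06 and GstD1 by 1.32. Without CS GH replicate 1 or Or67d GH replicate 3, 5 were higher. cry was higher than in CS in GH as well, by a log2 change of 1.34, and Clk by 1.04.

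The fru mutant was compared with CS next, with the same limit on strain background. The lysosomal sulfatase gene Sgsh (FBgn0038660, 3R 18911053 to 18912922) rose from 3.1 ± 0.604 CPM in CS GH to 33.9 ± 0.191 (log2 3.45 ± 0.152, SE, n = 3 per group, edgeR adjusted p = 6.47e-14) and by 2.89 ± 0.149 in SH (adjusted p = 1.32e-12). NT5E-2 (3.18 ± 0.156 and 3.45 ± 0.157), HIP-R (1.40 ± 0.102 and 1.47 ± 0.102) and CG31817 (3.33 ± 0.227 and 3.40 ± 0.229) also rose in both housings. NT5E-2 and CG31817 were called higher in every mutant in both housings, and Sgsh in every mutant in SH, so these rises were not particular to fru. Sgsh lies on 3R, as fru does. sordd2 stood at 72.1 ± 10.2 CPM in GH and 68.4 ± 8.28 in SH against 0.00802 ± 0.0139 and 0 in CS, at least 3.41e+03-fold higher in SH. CG6912 fell by a log2 change of -6.18 ± 0.185 and -5.50 ± 0.177 (adjusted p = 6.93e-17 and 3.71e-16), sand, which encodes a potassium channel, by -9.34 ± 0.313 and -8.53 ± 0.293, and Spindly by -3.45 ± 0.194 and -3.44 ± 0.196. CG6912 overlaps asRNA:CR45600, sand overlaps uno and Spindly overlaps CG8852. The neuropeptide genes Crz (corazonin, 1.14 and 1.42) and AstA (allatostatin A, 0.85 and 1.06) rose in GH and SH, and Ilp5 rose in GH by 2.48. Crz was called higher in every mutant in both housings, and sand lower in every mutant in GH. These changes were therefore not particular to fru either.

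Between fru and CS, 1056 genes were higher and 862 lower in GH and 842 and 690 in SH, with 528 higher and 397 lower in both. The 1918 calls in GH became 1277 without fru GH replicate 3 and 1247 among the notAC libraries, and the 1532 in SH became 994 without fru SH replicate 3 and 923 among the notAC libraries. Without the batch term they were 1109 and 846, and with only the groups compared 776 and 589. Of 40 neuropeptide genes, 13 were higher and 2 lower in GH (14 and 2 when adjusted over the list alone; camera adjusted p = 0.002, but adjusted p = 0.837 with an estimated correlation). In SH, 9 were higher and 1 lower (11 and 3 when adjusted over the list alone), 5 higher and 3 lower without fru SH replicate 2, 3 lower without CS SH replicate 3 and 2 lower without fru SH replicate 3. Of the immune effector genes, 6 were higher in GH (6 when adjusted over the list alone) and 19 of 40 in SH (25 when adjusted over the list alone; camera adjusted p = 1.36e-13, but adjusted p = 0.891 with an estimated correlation), among them the Turandot stress genes TotA (4.29 in SH) and TotC (7.60 in SH). Of 77 cytochrome P450 genes, 24 were higher and 6 lower in GH (29 and 6 when adjusted over the list alone; camera adjusted p = 0.00089, but adjusted p = 0.837 with an estimated correlation), with 12 higher without CS GH replicate 3 and 15 without fru GH replicate 3.

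The limit on strain background holds for the dsx mutant as well, which is labelled w-. In the dsx mutant, CG14692 (FBgn0037836, 3R 10794058 to 10803955) rose from 0.748 ± 0.0668 CPM in CS GH to 319 ± 19 (log2 8.90 ± 0.37, SE, n = 3 per group, edgeR adjusted p = 1.71e-14) and by 8.13 ± 0.357 in SH. The zinc transporter gene ZnT77C rose by 4.01 ± 0.196 and 3.52 ± 0.192, and cGlr2, a sensor gene of antiviral immunity, by 1.81 ± 0.101 and 1.59 ± 0.0993. spartin (FBgn0037265, 3R 4654800 to 4657985) fell by a log2 change of -2.10 ± 0.087 and -1.83 ± 0.0874 (adjusted p = 1.71e-14 and 2.36e-13), CG6912 by -6.15 ± 0.184 and -6.11 ± 0.186 and sand by -6.91 ± 0.249 and -6.44 ± 0.247, the last 2 with the overlaps named above. The yolk protein genes Yp2 and Yp3, which in adults are products of the female fat body, rose by 5.07 and 5.12 in GH, with Yp2 up by 6.63 and Yp3 also called in SH, and fit, another female-biased gene that overlaps CG31465, by 4.22 and 4.26. Obp99b, which is male-biased, fell by a log2 change of -2.34 in GH and -5.12 in SH. Of 8 sex-biased fat body genes, 4 were higher and 1 lower in each housing over all genes tested (4 and 1 in GH and 4 and 2 in SH when adjusted over the list alone; camera adjusted p = 0.0226 in GH, but adjusted p = 0.873 with an estimated correlation).

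In dsx brains, called genes for protein synthesis and respiration were mostly lower, and called genes of the synapse were higher. In SH, 65 of 85 cytosolic ribosomal protein genes were lower and 3 higher (68 and 3 when adjusted over the list alone), with a median log2 change of -0.555, and of 67 nuclear-encoded oxidative phosphorylation genes 53 were lower and 2 higher, with a median of -0.507. camera gave adjusted p values of 6.3e-10 and 2.31e-11 for these lists in SH, and 0.684 for both with an estimated correlation. In GH the lower genes were 33 and 36 (41 and 40 when adjusted over the list alone), and with the deposited normalized values and limma they were 5 and 10 in GH and 57 and 38 in SH. The 33 became 19 without CS GH replicate 1, 15 without CS GH replicate 2, 20 without dsx GH replicate 1 and 17 without dsx GH replicate 2, and the 36 became 20 without CS GH replicate 2 or dsx GH replicate 2. In SH, 16 of 25 synaptic vesicle genes were higher and 0 lower (18 when adjusted over the list alone; camera adjusted p = 1.35e-06, but adjusted p = 0.684 with an estimated correlation), among them Syt1 (0.86) and cpx (1.12). Of 32 dpr and DIP genes, which encode neuronal cell-surface proteins, 23 were higher and 1 lower in SH (24 and 1 when adjusted over the list alone), 15 of them without CS SH replicate 3. In GH, 8 synaptic vesicle genes were higher (8 when adjusted over the list alone; camera adjusted p = 0.00101, but adjusted p = 0.873 with an estimated correlation), 3 without CS GH replicate 1 and 1 without CS GH replicate 2 or any dsx GH library. The share of mitochondrially encoded counts was 12.3% to 14% in the dsx libraries against 4.37% to 10.1% in CS GH and 2.95% to 4.53% in CS SH. With that share as a covariate, 36 ribosomal protein and 36 oxidative phosphorylation genes were lower in SH (23 and 27 in GH), with medians of -0.518 and -0.513. Synaptic vesicle genes then had 3 higher in SH and 1 in GH, and dpr and DIP genes 2 in SH. In SH the medians of these lists fell from 0.36 to 0.193 and from 0.383 to 0.181, and the median SE of their genes grew from 0.122 to 0.161 and from 0.106 to 0.145, and in GH the synaptic vesicle median fell from 0.157 to 0.0682 (median SE 0.122 both times). For the ribosomal and oxidative phosphorylation genes in SH the median SE grew from 0.138 to 0.197 and from 0.112 to 0.16.

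In dsx GH, 11 of 19 heat shock genes were higher (15 when adjusted over the list alone; camera adjusted p = 0.000361, but adjusted p = 0.873 with an estimated correlation), with Hsp26 at 2.83 and Hsp22, which overlaps CG4456, at 2.59 on the log2 scale. This count was 6 without CS GH replicate 1, 6 without CS GH replicate 2 and 2 without dsx GH replicate 1. In total 915 genes were higher and 1534 lower in GH, and 2112 and 2633 in SH, with 689 higher and 1266 lower in both. Among the genes of the main test in GH, the deposited normalized values with limma gave 1200 higher and 853 lower, and DESeq2 size factors in edgeR gave 1079 and 1240. With only the groups compared, 4084 genes were called in GH. All dsx libraries were notAC, so the batch term rested on the other genotypes. With the share of mitochondrial counts as a covariate, an alternative chosen after seeing the data, 1635 genes were called in SH in place of 4745, and the calls of Yp2, Yp3 and cpx in SH were lost.

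A comparison of chromosome arms asked whether calls lie near the mutated gene. For Or47b, on 2R, 5.87% of the tested genes of that arm were called in the same direction in both housings against 1.48% elsewhere (Fisher's exact test, 2-sided, odds ratio 4.17, 95% confidence interval 3.24 to 5.37, adjusted p = 8.6e-28), and 2L stood at 4.52%. For Or67d, on 3L, the shares were 7.13% and 2.69% (odds ratio 2.78, interval 2.24 to 3.43, adjusted p = 4.84e-20), and 3R stood at 5.82%. For fru (8.28% on 3R and 8.18% elsewhere, odds ratio 1.01, adjusted p = 0.873) and dsx (17% and 17.4%, odds ratio 0.975, adjusted p = 0.873) the arm of the mutated gene did not stand out. These tests treat genes as independent, which neighbours need not be.

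**Figure D5:**
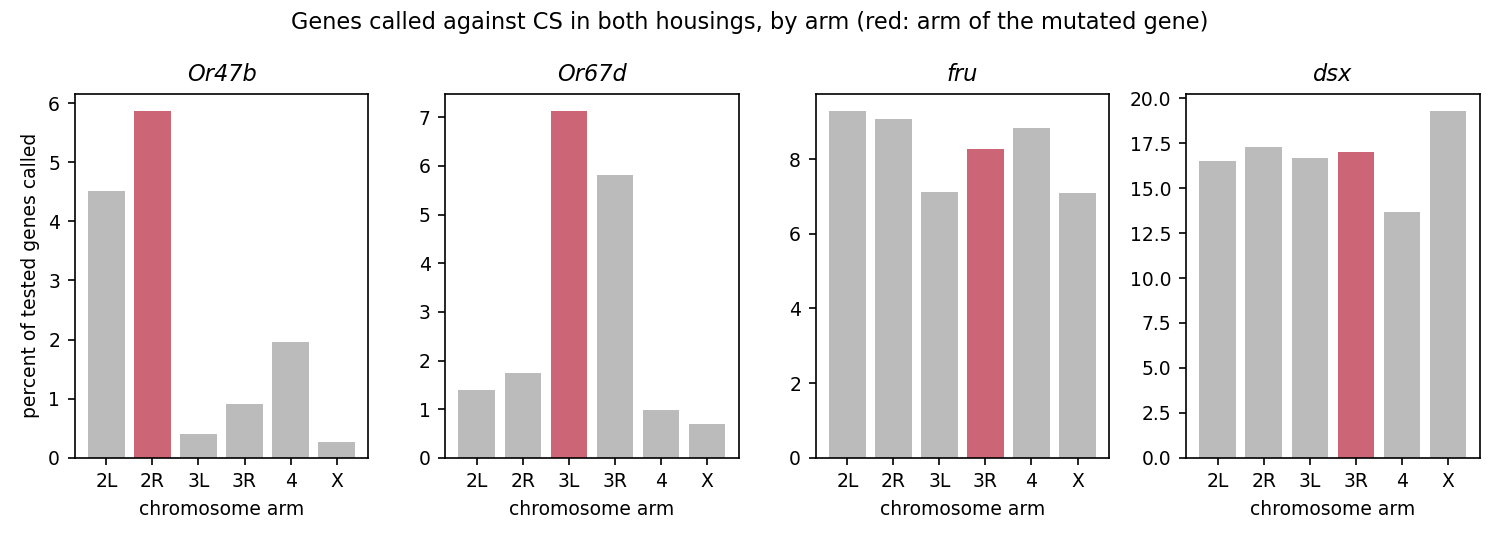
Share of tested genes called in the same direction in both housings (y axis, percent) on each chromosome arm (x axis) for the 4 mutants against CS, with the arm of the mutated gene in red. Or47b peaks on 2R (5.87%) and Or67d on 3L (7.13%), whereas the fru and dsx bars are of like height.

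Interaction terms tested whether the housing change itself differed from that in CS. CG10513, which rose in isolated CS males, differed in Or67d by a log2 difference of -1.38 ± 0.18 (edgeR adjusted p = 0.000597), in fru by -1.89 ± 0.181 (adjusted p = 3.92e-06) and in dsx by -1.53 ± 0.181 (adjusted p = 0.000176), with n = 3 per group. Its levels were 70.7 ± 7.31 in Or67d GH and 72.7 ± 10.8 CPM in Or67d SH. By library, CG10513 was 36.5 to 39.5 CPM in CS GH and 46.2 CPM or more in every library of the other groups. Each interaction subtracts the same CS libraries, so calls of a gene in several mutants are not separate evidence. Ugt35B1 differed in Or67d (-1.31 ± 0.173, adjusted p = 0.000597) and fru (-1.35 ± 0.173, adjusted p = 0.000242), and CG9377 in Or67d (-1.74 ± 0.278, adjusted p = 0.00577) and fru (-2.75 ± 0.28, adjusted p = 6.31e-06). cry differed in Or67d (-1.14 ± 0.159, adjusted p = 0.000952). These calls kept their side of the threshold with each of the 12 libraries of the comparison left out, although Ugt35B1 in fru was lost with only the 4 groups fitted.

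By count, the log2 difference from the CS housing change was positive for 1 gene and negative for 1 in Or47b (935 at an unadjusted p under 0.05; 21 called by DESeq2), 4 and 16 in Or67d (1617; 103), 3 and 22 in fru (915; 100) and 0 and 1 in dsx (1506; 101). Dsk was not among them in any mutant (log2 difference from -0.24 to 0.08, adjusted p from 0.708 to 0.954). Both Or47b calls were unstable, since CG14125 was lost without CS GH replicate 3, CS SH replicate 2, Or47b GH replicate 3 or Or47b SH replicate 3, the 4 AC libraries of the comparison, and CG10513 in Or47b (-1.04 ± 0.179, adjusted p = 0.0358) was lost without any library but CS GH replicate 2 and Or47b GH replicate 1. The 20 calls in Or67d became 208 without Or67d SH replicate 1, 34 without CS GH replicate 2, 8 without CS GH replicate 1, 9 without CS SH replicate 2, 7 without CS SH replicate 3, 9 without Or67d GH replicate 2, 10 without Or67d GH replicate 3, 8 without Or67d SH replicate 2 and 10 without Or67d SH replicate 3. The 25 in fru became 56 without CS GH replicate 3, 49 without fru SH replicate 2, 15 without fru GH replicate 2 and 13 without CS GH replicate 1, CS SH replicate 2 or CS SH replicate 3. The 1 in dsx, CG10513, became 15 genes without CS GH replicate 3, 6 without CS GH replicate 2, 3 without CS SH replicate 1, 6 without dsx GH replicate 3 and 5 without dsx SH replicate 2. With only the groups compared, the counts were 3 in Or47b, 5 in Or67d, 3 in fru and 283 in dsx.

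A further comparison asked whether a mutation moves the grouped brain the way isolation does. Of the 210 genes called for housing in CS, 202 had the same sign in Or67d GH against CS GH, 184 in fru, 157 in Or47b and 117 in dsx, and 121, 113, 29 and 40 were also called in that direction, of 123, 117, 32 and 56 called in both comparisons in either direction. cry and CG10513 were called higher in both comparisons, with cry at 43.3 ± 1.13 CPM in CS GH, 80.9 ± 4.4 in CS SH and 108 ± 8.5 in Or67d GH. The same CS GH libraries enter both sides, so shared signs arise with no effect at all. In 20 simulations of unchanged groups, the 210 genes with the smallest p for housing had the same sign in 195 to 197 genes on average, depending on the mutant. Without a housing effect, those genes were picked by spread, which the shared CS GH libraries carry into the mutant comparison as well. So 195 to 197 sets no level for the 210 genes called in CS. The simulations gave 0.05 to 0.15 genes called in both in the same direction, but with only 0.2 calls per mutant on average they set no level for those counts. The covariance across genes is also given beside the simulated one. It was 0.297 against 0.0874 in Or67d, with a jackknife SE of 0.149, 0.212 against 0.0864 in fru (SE 0.163), 0.175 against 0.0876 in Or47b (SE 0.139) and 0.122 against 0.0845 in dsx (SE 0.164). None of the 4 differences from the simulated value exceeded 2 jackknife SE. Each covariance lay above the highest of the 20 simulated ones, which was 0.104 in Or67d, 0.0971 in fru, 0.0974 in Or47b and 0.106 in dsx. These 2 measures of spread disagree, so an excess is neither shown nor excluded. The correlations across genes, which are not independent replicates, were 0.508, 0.301, 0.302 and 0.179 in the same order, against simulated ones of 0.51, 0.521, 0.52 and 0.507. The simulated correlations come from groups without real changes, so they set no level for these.

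The last comparison counted genes changed alike in the mutants. In GH, 53 genes were called in the same direction in all 4 mutants against CS, 34 higher and 19 lower, and in SH 46, 28 higher and 18 lower. Among them, CG31817 rose in each, from 1.05 ± 0.134 CPM in CS GH to between 7.18 ± 1.69 and 10.6 ± 0.75, NT5E-2 rose from 2.16 ± 0.0907 CPM to between 4.77 ± 0.563 and 19.9 ± 3.46, and prg fell from 28.8 ± 2.45 to between 9.93 ± 0.215 and 20.7 ± 1.84. pre-lola-G fell from 63.2 ± 9.45 CPM to between 8.58 ± 1.92 and 19.7 ± 0.811, although it overlaps lola. Independent lists would give 0.188 in GH and 0.38 in SH. Simulated unchanged groups against the same CS libraries gave 0, but with only 0.2 and 0.138 calls per mutant on average they had too few to set a level for this count. With 3 CS libraries per housing the controls cannot be split, so part of the excess may come from the shared controls. By pair, fru and Or67d shared 303 higher genes in GH (54.2 expected of independent lists) and fru and dsx 304 lower ones (117 expected).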

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

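The tests of transposon insertions and of all features together were chosen only after the counts were seen, whereas the interactions, their splits and the chromosome arm tests were planned.

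The interaction terms stand here because each tested whether the housing effect of a mutant differed from that of CS, and each called at least 1 gene with edgeR. They called 2 genes in Or47b, 20 in Or67d, 25 in fru and 1 in dsx. Among 25 splits that exchanged housing among the libraries of the mutant and among those of CS, the real one included, 2 gave as many genes as the real 2 in Or47b (highest other 9), and 3 gave as many as the real 20 in Or67d (highest other 523). In fru 2 splits gave as many as the real 25 (highest other 714), and in dsx 5 gave as many as the real 1 (highest other 33). Chance cannot be excluded for any of the 4 counts. Splits that called several times the real count point to a structure of the samples, whose source was not tested.

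Transposon insertions form a signal outside the gene tests. Of 1333 insertions that passed the filter when all features were tested together, edgeR called 106 between Or47b and CS in GH (37 higher, 69 lower), 197 in Or67d (57 and 140), 327 in fru (128 and 199) and 387 in dsx (233 and 154). In SH the counts were 145 in Or47b (75 and 70), 181 in Or67d (78 and 103), 293 in fru (159 and 134) and 549 in dsx (411 and 138). Housing called 12 insertions in CS, each lower in SH, 2 in Or67d and 3 on average over genotypes. It called 0 in Or47b (52 at an unadjusted p under 0.05), 0 in fru (118) and 0 in dsx (37). Insertions share reads with near-identical copies, so a call names a family of copies more than a site, and strains can carry different insertions. No explanation was tested for these calls, and no other tool was run on the insertions.

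Genes changed in both housings in the Or47b and Or67d mutants clustered on the chromosome of the mutated gene. The odds ratio of the arm against the others was 4.17 in Or47b (2R) and 2.78 in Or67d (3L), and the other arm of the same chromosome was raised as well (4.52% on 2L and 5.82% on 3R). Within 2 Mb of the gene 5.21% of genes were called in Or47b against 2.25% in the rest of the genome (adjusted p = 0.00163) and 5.78% in Or67d against 3.47% (adjusted p = 0.0271), but these shares lay below those of the whole arm (5.87% and 7.13%), so they do not single out the neighbourhood of the gene. A chromosome that differs from CS in background may therefore account for part of these calls, and an effect of the receptor on genes of its chromosome was not tested. For dsx the odds ratio of 0.975 argues against a cause confined to its arm, and genes within 2 Mb were called less often than elsewhere (12.1% against 17.5%, adjusted p = 0.00954). For fru the odds ratio was 1.01 (95% CI 0.863 to 1.19), with 7.84% within 2 Mb against 8.21% and 7.09% to 9.29% on each arm, which argues against a cause confined to its arm as well. The bound set beforehand also asked for an odds ratio of 1 or less, so a small excess on the arm cannot be told apart from none. A background that differs alike from CS on every arm stays open for fru and dsx. In Or47b the calls were 0.266% to 1.96% on 3L, 3R, 4 and X, and in Or67d 0.693% to 1.75% on 2L, 2R, 4 and X. These values argue against such a background in Or47b and Or67d, although smaller differences on those arms stay open.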

How the results depend on the processing

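The test of all features, the notAC libraries alone, the deposited normalized values with limma and the mitochondrial share as a covariate were chosen only after the data were seen. The other settings were planned.

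Or47b stayed near the floor of 3 counts in CS, so its loss could not be read at this depth. The gene-wise results kept their direction almost throughout. Of 921 pairs of a named gene and a comparison, 901 kept their call with DESeq2 size factors, 861 without a filter on low counts, 908 with DESeq2's Wald test, 654 without the batch term and 867 with all features tested. Of 865 pairs, 614 kept it with only the groups compared, of 915 pairs 683 among the notAC libraries, and of 908 pairs 816 with the deposited values. With the mitochondrial covariate 724 of 921 kept it. Over the planned settings other than single libraries, 541 pairs were never lost and 380 were lost at least once, and with single libraries left out 591 and 330. Jon65Aiii in fru GH reversed from a log2 change of -5.57 to 0.0532 without CS GH replicate 3, with a range from -6.34 to 0.0532 over single libraries left out. Yp2 in fru SH reversed from 5.1 to -0.0181 among the notAC libraries and to -0.0116 without fru SH replicate 3, with a range from -0.0116 to 6.26. In both genes 1 library set the value, and the cause was not tested.

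DESeq2's Wald test called more genes for housing, with 663 in CS, 42 in Or47b, 18 in Or67d, 82 in fru, 26 in dsx and 230 on average. Its interaction counts were 21 in Or47b, 103 in Or67d, 100 in fru and 101 in dsx. It gave 49 genes shared between genotypes for housing, in place of 16, and 72 changed alike in all 4 mutants in SH, in place of 46. The covariance of mutant and isolation effects was 0.332 in Or47b, 0.473 in Or67d, 0.346 in fru and 0.29 in dsx with DESeq2. Without a filter on low counts it was 0.698, 0.791, 0.725 and 0.537 in Or47b, Or67d, fru and dsx, and the dsx interaction had 2 genes. The cause was not tested for these, except that the unfiltered values include genes of few counts.

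Without the batch term, housing called 46 genes in CS, 9 in Or47b, 1 in Or67d, 5 in fru, 1 in dsx and 53 on average. Against CS in GH it called 230 in Or47b, 608 in Or67d and 1109 in fru, and in SH 306 in Or47b and 846 in fru. The interactions had 0 genes in Or47b, 6 in Or67d and 8 in fru. Shared housing genes numbered 7, and genes changed alike in all 4 mutants in GH 33. The batch then adds to the spread within CS, Or47b and fru groups, by construction.

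With only the groups compared, which leaves few libraries to estimate the spread, housing called 17 genes in CS, 0 in Or67d, 5 in fru and 57 in dsx. Against CS in GH the counts were 139 in Or47b, 776 in fru and 4084 in dsx, and in SH 534 in Or47b, 134 in Or67d and 589 in fru. The interactions had 5 genes in Or67d, 3 in fru and 283 in dsx. The spread was then estimated from these libraries alone. By the lowest chi-square per degree of freedom of a replicate pair, dsx replicates were the most alike (15.1 in GH and 16.7 in SH, against 38.4 to 284 in other groups). Whether this raised the counts in dsx was not tested.

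Among the notAC libraries, which are fewer, housing called 70 genes in CS, 5 in Or47b, 7 in Or67d, 10 in fru and 5 in dsx. Against CS the counts were 284 in Or47b and 1247 in fru in GH, and 304 and 923 in SH. The interactions had 1 gene in Or47b, 11 in Or67d and 4 in dsx, 7 housing genes were shared, and 28 genes changed alike in all 4 mutants in SH. For the gains in Or67d and dsx the cause was not tested. The single AC pair of CS, Or47b and fru had the same sign as the fit for 210 of 210, 24 of 24 and 19 of 19 called genes, although these libraries are in the fit.

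With the mitochondrial share as a covariate, 70 genes were called for CS housing, 356 in Or47b SH and 1635 in dsx SH against CS. The interactions had 0 genes in Or47b, 5 in Or67d and 2 in dsx, 10 housing genes were shared and 30 changed alike in all 4 mutants in SH. Tested with all features, housing called 5 genes in Or67d and 12 in fru. With the deposited normalized values, housing called 9 in Or67d, and the interactions 1 in Or47b (0 positive, 1 negative), 34 in Or67d and 12 in dsx (4 positive, 8 negative). The cause was not tested for these. No scaling moved the median change of all genes by over 0.1 on the log2 scale.

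Of the camera calls over 36 lists and 18 comparisons, 3 were left with an estimated correlation, and fry made 51 calls. The estimated correlation widens the test by construction, and fry asks another question.

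Replicate numbers do not pair the samples, as same-numbered GH and SH libraries had correlations from -0.23 to 0.17, with 1 of 15 pairs over 0.1. A block for the replicate number gave 12 calls for fru housing, 0 for the Or47b interaction and 7 for the dsx interaction, and 851 of the 921 pairs kept their call. Every other count stayed within 1.5 times of the main one, as with 176 in CS and 16 in Or47b for housing.

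With each library of a comparison left out in turn, housing calls ranged from 52 to 436 in CS, 10 to 22 in Or47b, 1 to 3 in Or67d, 5 to 135 in fru, 1 to 4 in dsx and 116 to 155 on average. Against CS in GH they ranged from 235 to 551 in Or47b, 660 to 1080 in Or67d, 1277 to 1912 in fru and 1651 to 2699 in dsx. In SH they ranged from 327 to 1069 in Or47b, 455 to 722 in Or67d, 994 to 1938 in fru and 3827 to 4470 in dsx. The interactions ranged from 0 to 4 in Or47b, 7 to 208 in Or67d, 13 to 56 in fru and 1 to 15 in dsx. The covariance with isolation ranged from 0.171 to 0.299 in Or47b, 0.282 to 0.435 in Or67d, 0.208 to 0.353 in fru and 0.105 to 0.258 in dsx. Fewer libraries tend to lower a count, and the cause of the rises was not tested.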

Other observations

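The tests of the immune, clock and mitochondrial explanations below were chosen only after the results were seen, and the list tests and the splits were planned.

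Some genes called but not named in the report are given first. Ilp3 was higher in dsx than in CS, by a log2 change of 2.40 in GH (edgeR adjusted p = 3.84e-07) and 1.36 in SH (adjusted p = 0.000182), and Ilp5 was higher in GH by 1.34 (adjusted p = 6.52e-05). The larval serum protein gene Lsp2 rose on average with isolation by 2.00 (adjusted p = 0.000267). The female-biased gene fit rose in fru SH by 3.92 (adjusted p = 2.68e-06), although its level was 63.3 CPM in replicate 3 and 15.7 CPM or less in the other fru SH libraries. Yp2 and Yp3 stood at 759 and 877 CPM in fru SH replicate 3, an AC library, and at 3 CPM or less in the other fru SH libraries. The transcription factor gene retn fell by a log2 change of -1.20 and -1.61 in Or47b GH and SH and by -1.68 and -1.59 in fru. In Or67d GH the haemocyte genes Hml (0.90) and PPO1 (1.46) and the glial transporter genes Mdr65 (1.00) and Tret1-1 (0.67) were higher than in CS. Without the batch term the calls of retn in Or47b and of Hml, PPO1 and Tret1-1 in Or67d GH were lost, and that of Tret1-1 also with only those groups fitted. CG14125, the gene with the smallest adjusted p for the AC batch, stood at 264 CPM in CS GH replicate 3 and 30.8 CPM in CS SH replicate 2, the AC libraries of CS, and at 0.0621 CPM or less in the other CS libraries.

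Lists of neuronal signalling genes had more calls higher than lower in dsx SH against CS SH, although most members of some were not called. Calls were 11 higher of 15 genes of cAMP signalling and memory (7 without CS SH replicate 2 or dsx SH replicate 1), with CaMKII at 1.53 on the log2 scale, 17 higher and 4 lower of 37 ion channel genes, 10 and 1 of 28 fast transmitter receptor genes, 12 and 4 of 38 neuropeptide receptor genes and 12 and 3 of 30 monoamine genes. Adjusted over the list alone they were 11, 18 and 4, 10 and 1, 12 and 4, and 12 and 6. The camera adjusted p was 0.000776, 0.0123, 0.000945, 0.0123 and 0.0705, and 0.684, 0.693, 0.684, 0.684 and 0.684 with an estimated correlation. The 1 lower transmitter receptor gene was lost without any 1 of the 6 libraries. With the mitochondrial share as a covariate, the calls were 1 higher for cAMP signalling and memory, 1 higher and 2 lower for ion channels, 3 higher for fast transmitter receptors, 4 higher and 3 lower for neuropeptide receptors and 2 higher and 2 lower for monoamine genes. Of 13 mitochondrially encoded genes 9 were higher and 2 lower (9 and 2 when adjusted over the list alone), with a median log2 change of 2.41 and a camera adjusted p of 0.00947 (0.684 with an estimated correlation), and the deposited normalized values hold none of them.

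Other lists in dsx SH gave 9 higher and 4 lower of 22 ecdysone genes (9 and 5 when adjusted over the list alone), the 4 becoming 2 without CS SH replicate 1 or replicate 2 and 1 without dsx SH replicate 2. They gave 6 and 4 of 38 chromatin regulators (5 and 4 when adjusted over the list alone), 0 and 3 of 6 eye pigment genes (0 and 3), 4 and 0 of 8 mushroom body markers (4 and 0, with 2 higher without CS SH replicate 2, CS SH replicate 3 or dsx SH replicate 3) and 1 and 2 of 7 trachea and cuticle markers (1 and 3, the 1 lost without dsx SH replicate 2). The camera adjusted p of these 5 lists ran from 0.0825 to 0.766. Of 24 photoreceptor markers 4 were higher and 11 lower there (4 and 11), with 5 lower without CS SH replicate 3, and 1 was higher with isolation in CS (10 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.000867, 0.428 with an estimated correlation). The 1 became 10 without CS SH replicate 1, 3 without CS GH replicate 2 and 0 without any other CS library.

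In fru GH, 8 of 10 digestive enzyme genes were lower (8 when adjusted over the list alone; camera adjusted p = 0.0797), but 1 without CS GH replicate 3 or fru GH replicate 3, 2 without fru GH replicate 1 and 5 without fru GH replicate 2. Insulin and starvation genes gave 5 higher of 19 (7 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.111), and 3 without CS GH replicate 3 or any fru GH library. Fat body markers gave 4 higher of 9 (4; camera adjusted p = 0.0141, 0.837 with an estimated correlation), with 2 without CS GH replicate 3 or fru GH replicate 3, and haemocyte markers 4 of 9 (6; camera adjusted p = 0.00603, 0.831 with an estimated correlation), with 2 without CS GH replicate 3. Odorant-binding protein genes gave 6 higher and 1 lower of 24 (6 and 1), 2 lower without CS GH replicate 3, and sex determination genes 2 lower of 18, fru and retn (2; camera adjusted p = 0.00781, 0.831 with an estimated correlation), or 5 without CS GH replicate 2. In fru SH, 8 odorant or ionotropic receptor genes of 34 were higher and 4 lower (8 and 4), with 2 lower without CS SH replicate 2 or fru SH replicate 3, and 2 of 4 neuroendocrine gland markers were higher (2), 1 of them without fru SH replicate 1 and 0 without any other of the 6 libraries. Of 7 antenna markers 6 were lower in Or47b SH (6; camera adjusted p = 0.00401, 0.882 with an estimated correlation), but 1 without Or47b SH replicate 2 and 0 without CS SH replicate 2 or Or47b SH replicate 3. In SH they were also lower in Or67d (2, or 3 when adjusted over the list alone), fru (4, or 5) and dsx (5, or 6), with camera adjusted p values of 0.0172, 0.0653 and 0.0517 (0.933, 0.921 and 0.684 with an estimated correlation), which without CS SH replicate 2 became 1, 0 and 3. Other single libraries took the 2 to 1 (any of Or67d SH), the 4 to 1 or 0 (fru SH replicates 1 and 3) and the 5 to 3 (dsx SH replicates 2 and 3). Of 13 glia markers 3 were higher in Or67d GH (6 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.0126, 0.664 with an estimated correlation), and 5 without CS GH replicate 3 or Or67d GH replicate 1. No camera call differed in sign from the list's median or mean.

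Immune effector genes fell with isolation in CS and Or47b, by a median log2 change of -2.05 and -2.42, and tissue carried along with the grouped brains was weighed first. The 18 fat body and haemocyte markers had a median change of 0.206 in CS (interquartile range 0.448) and 0.0728 in Or47b (interquartile range 0.257), which argues against such tissue as the source, although fat body can itself express immune genes. Of the genes called, at least 7 of 15 in CS and 4 of 10 in Or47b stayed called with any 1 library left out, which argues against 1 library that stands apart as the whole cause. A lower exposure of isolated males to microbes may account for the fall and was not measured.

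The clock genes followed an order in CS. Of 7 clock genes, 7 had the sign that antiphase cycling gives, with Clk and cry higher and per, tim, vri, Pdp1 and cwo lower. The signs of the 4 called genes were known when this order was tested, so only 3 signs were free, too few to set the order apart from chance. Collection of the 2 groups at different times of day and a shift of the fly's own clock with isolation cannot be told apart, since the labels give no time of collection. Housing in the mutants gave the same orientation in 6 of 7 genes in Or47b and dsx and the opposite one in 6 of 7 in Or67d and 5 of 7 in fru. There edgeR and DESeq2's Wald test each called 0 of the 7 genes in each mutant (1, 2, 0 and 4 at an unadjusted edgeR p under 0.05 in Or47b, Or67d, fru and dsx), and the median sizes were 0.0851 to 0.343 on the log2 scale against 0.847 in CS. The difference from CS in the housing effect was called by edgeR in 2 of the 7 genes in Or67d and 1 in fru, and in 0 in Or47b and dsx (3 each at an unadjusted p under 0.05, and 1 each with DESeq2's Wald test). Against CS GH, the order held in 7 of 7 genes in Or67d GH and fru GH, 6 of 7 in Or47b GH and 4 of 7 in dsx GH, but these comparisons share the CS GH libraries with CS housing, so the agreement is no separate evidence. Every CS GH library lay apart from every other library in vri (48.1 to 78.2 CPM against 39.1 or less), Clk (5.31 to 6.46 against 7.15 or more) and cry (42.5 to 44.6 against 45.2 or more), but not in tim, which was 136 to 201 CPM in CS GH and 245 to 277 in dsx GH. Clk was called higher in all 4 mutants in GH (largest adjusted p 0.0353). With the mitochondrial share as a covariate the median size of the 210 CS changes kept 0.883 of its value (0.604 to 0.533, median SE 0.129 to 0.137) and 210 of 210 kept their sign, which argues against that share as the whole cause, although 60 of the 210 stayed called, as the changes shrank slightly and their errors grew.

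For comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05, and 1 split, the real one, reached the real count in each. The real count and the highest of the other splits were 210 and 179 for housing in CS, 24 and 0 in Or47b, 3 and 1 in Or67d, 19 and 2 in fru and 2 and 0 in dsx. Against CS in GH they were 427 and 4 in Or47b, 1101 and 0 in Or67d, 1918 and 93 in fru and 2449 and 1 in dsx, and in SH 950 and 1, 636 and 0, 1532 and 2 and 4745 and 1. The CS split with 179 calls set both AC libraries with CS SH replicate 1 against the rest, and within notAC the real split gave 70. For the averaged housing effect 1 of 50 splits, the real one with 144 genes, reached that count (highest other 1). This share, the smallest that 50 splits can give, is under 0.05 and argues against chance there.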
